A study of Mus musculus with 24 samples.

How the data were processed

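Gene expression was measured in sorted mouse thymocytes cultured with or without interleukin 7 (IL7). Per the labels, DN3a, DN3b and DN4 cells were taken from C57BL/6J mice with an intact IL7 receptor gene in 4 independent sorts. Every sort gave an untreated and an IL7-treated culture of each subset, so that 6 groups of 4 cultures were analysed on 24 arrays. The authors' text also speaks of technical replicates without naming arrays, so n, SE and p take these 4 sorts as independent, as labelled. Per the labels' protocols, 250 ng of total RNA per culture was amplified, biotinylated and hybridised to Illumina mouse Ref8v2 beadchips.

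The deposited table of scanner values holds a linear signal intensity for each of 25697 probes on each array, and per the file headers a detection p-value stands beside each intensity. A detection p-value gives the rank of the probe among the negative-control beads of its array. GenomeStudio 2011.1 and R Bioconductor 2.13.0 are the versions named in the submitters' processing notes and design text. The intensities differed between arrays in their medians, from 93.3 to 119.8, and had not been normalized between arrays. A second deposited table holds the authors' processed log2 values of the same arrays. Their design text states background subtraction, quantile normalization and log2 transformation. All 24 columns of that table had the same median of 6.734 and held the same sorted values, and the largest gap between them and the log2 of the quantile-normalized, uncorrected intensities was 0.049. The authors' log2 values therefore matched quantile normalization without a visible background subtraction, with no centring and with higher values for more signal. Each of the 24 processed columns correlated best with the intensities of its own array, with a lowest correlation of 0.967. Number of other per-sample columns left unused: 0.

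The intensities were corrected and normalized again with neqc in limma 3.58.1 under R 4.3.3. This method estimates the background from negative controls, here inferred from the detection p-values, adds an offset of 16, quantile-normalizes the arrays and takes log2. The offset, and any background left uncorrected, compress the log2 changes of dim probes. Probes were named through the platform annotation, with symbols updated through gene identifiers: 23978 probes had 1 symbol, 0 had several and 1719 had none, and 23962 were looked up through a gene identifier. A probe was kept where its detection p was under 0.05 on at least 4 of the 24 arrays, which left 12939 probes, 12158 of them named. For each of the 8820 genes, the probe with the highest mean level stood for the gene. More than 1 kept probe existed for 2348 genes. For the genes named in the text, the other probes gave the same call in 151 cases, a different call in 50 and the opposite sign in 16. Pim1, Itgae, Pfkm, Cd6, Nav1, Bbc3, Jak3 and Bcl2l11 were among those with an opposite sign in at least 1 comparison. Where no kept probe of a gene was detected on any array of 1 group, a lower bound is given as "at least N-fold". It sets the mean of the brighter group against the mean, per array, of the lowest signal among detected probes or the gene's own signal, whichever was higher.

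IL7 effects and their differences between subsets were fitted with limma (lmFit and eBayes) over all 24 arrays, with the 12 culture pairs as blocks. Comparisons between untreated subsets were fitted over the 12 untreated arrays, with the 4 sorts as blocks. Adjusted p-values are Benjamini-Hochberg values over the 8820 genes with a threshold of 0.05, and SE is limma's moderated standard error. The authors' design text also names paired moderated tests. Whether the sort numbers pair the cultures was checked from deviations from the group means. Cultures of the same subset and sort correlated at 0.24 or more (median 0.47). All cultures of the same sort, these pairs included, had a median of 0.38, and cultures of different sorts and groups had a median of -0.089. Each of the 24 arrays correlated best with its own sort.

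The text names genes by a rule. In each of the 6 main comparisons it takes the 8 rising and the 8 falling genes with the largest log2 change among those past the threshold and changed the same way in all 4 sorts. For each difference of IL7 effects it takes the 4 largest on each side. Up to 4 members of each gene list are named. Cish, Socs1, Pim1, Bcl2, Bcl2l1, Mcl1, Bcl6, Il7r, Myc, Rag1, Cd4, Cd8a and Ptcra are considered in the IL7 comparisons whatever their values, and another gene of this part of the rule is not reported here. Genes with only clone or predicted-gene names were passed over. Il2ra, Tfrc and Kit mark the sort gates and are named only as gate checks, while Il2ra also counts in the Notch and the IL7 and STAT5 lists. No named probe stood for Kit, and the probes of Cd4 and Cd8a were detected on 0 arrays.

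25 gene lists were tested in each comparison with camera, which asks whether the genes of a list moved more than all other genes, at a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were alternatives. The lists were the IL7 and STAT5 response, FOXO-linked and quiescence genes, DN to DP differentiation, Notch targets, early genes induced by antigen receptors, V(D)J recombination, cytokine receptor and JAK-STAT components, the BCL2 family, glycolysis, cholesterol synthesis, ribosome biogenesis and MYC-linked growth, amino acid supply and ATF4, G1/S and DNA replication, G2/M, the type I interferon response and heat shock. The others were markers of early thymic progenitors, erythroid cells, B cells, myeloid cells, dendritic cells, NK and cytotoxic cells, gamma-delta T cells, mature T cells and thymic stroma. The lists overlap, so their tests are not independent: Rag1 and Rag2, for example, are on the FOXO-linked, DN to DP and V(D)J lists. Counts of list members past the threshold are given over all genes and, in brackets or a clause, adjusted over the list alone. The sample groups, the fits, the named-gene rule, the lists and the alternatives listed here were chosen before the data were examined.

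The calculations were tested on simulated data with 67, 67 and 66 genes shifted by 0.5, 1 and 2 log2 units. For the IL7 effect in DN3a, 70.1%, 89.6% and 100% of them were recovered. For the difference of the IL7 effect between DN4 and DN3a the shares were 35.8%, 86.6% and 98.5%, and for untreated DN4 against DN3b 59.7%, 95.5% and 100%. False calls numbered 10 of 183, 8 of 155 and 12 of 182. Camera at the preset correlation was run on the same simulated data with 24 lists of 20 random genes, 1 of them shifted by 0.5. It called the shifted list in all 3 comparisons, and 1, 0 and 1 of the other lists in the order above.

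The alternatives were another background correction (normexp, offset 50), none, the authors' values, no filter on dim probes, a filter of detection p under 0.01 on at least 12 arrays, other probe rules, fits without the block, with the sort as the only block or as a random effect, fits on the arrays of 1 comparison alone, a trended and robust variance, array weights, and leaving out each sort. A paired test per gene without moderation, unlike the paired moderated tests of the authors' text, was run on the same values and counted at an unadjusted p under 0.05 and after adjustment. Between 42.57% and 45.37% of probes were detected per array. The number of arrays, 4 per group, limits the precision.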

Results

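Transcript levels were measured in 3 successive stages of early T cell development in the mouse thymus. Thymocytes that carry neither CD4 nor CD8 are called double negative (DN). Per the labels, all sorted cells were negative for lineage markers and for KIT. DN3a cells were CD25-positive, low in CD71 and small, DN3b cells were CD25-positive, high in CD71 and large, and DN4 cells had lost CD25 and were high in CD71 and large. DN3a cells precede beta-selection, the checkpoint at which cells with a working T cell receptor beta chain proceed, and DN3b and DN4 cells follow it. After each of 4 independent sorts, the cells were rested for 1 h and cultured for 3 h without cytokine or with 10 ng/ml of IL7, a cytokine that signals through JAK kinases and STAT5. Illumina beadchips, on which beads carry gene-specific probes, measured RNA from each culture. This gave 6 groups of 4 arrays, 24 in all, and 8820 genes with a named probe above background on at least 4 arrays. The number of arrays limits the precision.

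Arrays of the same group correlated between 0.9783 and 0.9926 across probes, and 0 pairs of arrays were identical. The first principal component carried 63% of the variance, the second 9.32% and the third 6.97%. Transcripts of other blood cells varied between sorts. Hba-a1, an alpha globin gene of red cell precursors, was detected on 12 of the 12 arrays of sorts 1 and 3, at log2 signals of 8.50 to 10.46, and on 0 of the 12 arrays of sorts 2 and 4. Granulocyte transcripts were highest in DN4 cells of sorts 2 and 3. In untreated DN4 cells the log2 signal of S100a8, a calcium-binding protein abundant in neutrophils, was 4.45, 12.39, 12.29 and 7.58 in sorts 1 to 4. Lyz2, which encodes lysozyme, was at 4.62, 8.01, 8.51 and 5.10 in the same arrays, and Ngp, a neutrophil granule protein, was at 4.84, 8.97, 8.82 and 5.08. S100a8 stood at 4.52, 8.09, 9.55 and 6.25 in untreated DN3a and at 4.53, 5.81, 7.66 and 4.42 in untreated DN3b cells of sorts 1 to 4, above background on 3 of 4 and 2 of 4 arrays.

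**Figure D1:**
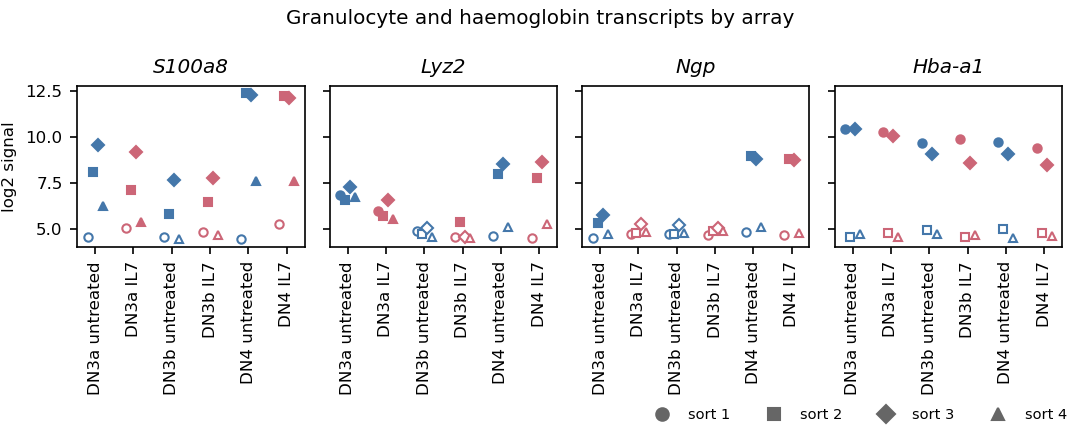
Log2 signal (vertical axis) of S100a8, Lyz2, Ngp and Hba-a1 on each of the 24 arrays, by subset, sort and treatment (horizontal axis), with filled points for arrays on which the probe was detected. S100a8 stood at 12.39 and 12.29 in untreated DN4 cells of sorts 2 and 3, and Hba-a1 was detected on the 12 arrays of sorts 1 and 3.

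The design first asked which transcripts IL7 changed in each subset. In DN3a cells IL7 raised Cish, which encodes an inhibitor of cytokine receptor signalling, 48.2-fold (log2 change 5.59 ± 0.15 SE, n = 4 culture pairs, limma adjusted p = 3e-10). Its relative Socs2 rose 37-fold (log2 change 5.21 ± 0.17 SE, adjusted p = 9.5e-10, with 2 of 4 untreated arrays above background). Bcl2, an inhibitor of apoptosis, rose 28.9-fold (log2 change 4.85 ± 0.14 SE, adjusted p = 3.5e-10). The kinase gene Map3k8 rose 10.8-fold, the prion protein gene Prnp 9.2-fold, the cytokine gene Osm 9.52-fold and the IL18 receptor gene Il18r1 at least 6-fold (adjusted p = 1.4e-06). For Osm, sort 3 lay apart at 2.59 against 3.43 to 3.54 in the other sorts. Khdc1c rose 16.1-fold, though its probe may also read near-identical members of its family. Among the transcripts that fell, Cpa3, a carboxypeptidase of mast cells and progenitors, had a log2 change of -2.23 ± 0.18 SE and Gpr183, an oxysterol receptor, of -2.06 ± 0.16 SE. The transcriptional repressor gene Bcl6 fell by 2.01 ± 0.10 SE on the log2 scale (adjusted p = 3.2e-08). Others were Blk (-1.65, with sort 1 apart at -1.22), Actn2 (-1.63), Itgae (-1.51) and Nrp1 (-1.38), while Pou2af1 was at least 1.83-fold lower (adjusted p = 6.9e-05).

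Of the genes considered in advance, Pim1, a kinase gene downstream of STAT5, rose 2.26-fold in DN3a cells (log2 change 1.18 ± 0.19 SE, adjusted p = 0.00059), although a dimmer second probe of Pim1 gave -0.17. Socs1 rose 1.79-fold (adjusted p = 0.0043), Bcl2l1 1.47-fold (adjusted p = 0.0029) and Myc 1.41-fold (log2 change 0.49 ± 0.13 SE, adjusted p = 0.018). The Myc call was lost under 5 alternatives. Mcl1 was at 0.27 ± 0.10 SE (adjusted p = 0.088), Rag1 at -0.19 (adjusted p = 0.29) and Ptcra at -0.20 (adjusted p = 0.52), none past the threshold. Il7r, the receptor's own gene, was at -0.14 ± 0.18 SE (adjusted p = 0.63), with sorts from -0.83 to 0.57 and a value of 0.08 without sort 4.

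8 of the 25 gene lists passed camera in DN3a cells. Of 14 measured genes of the IL7 and STAT5 response, 13 rose and 0 fell (14 adjusted over the list alone; camera adjusted p = 3.5e-16). Besides Cish, Socs2 and Bcl2, Lta rose by 1.60 ± 0.24 SE. Amino acid supply and ATF4 genes followed, with 16 of 22 risen and 1, Ddit4, fallen (17 and 2 adjusted over the list alone; camera adjusted p = 8e-15). Chac1, which degrades glutathione, rose by 3.16, Trib3 by 2.23, Cebpb by 2.21 and Slc7a5, a large neutral amino acid transporter, by 2.07 on the log2 scale, with Chac1 above background on 3 of 4 untreated arrays. In ribosome biogenesis and MYC-linked growth, 15 of 24 rose and 0 fell (17 adjusted over the list alone; camera adjusted p = 2e-12), among them the spermidine synthase gene Srm (1.53 ± 0.07 SE), Rrp12 (1.19) and Bop1 (0.96). In cholesterol synthesis 11 of 18 rose and 0 fell (11 adjusted over the list alone; camera adjusted p = 1.4e-08), including Mvd (1.02 ± 0.10 SE), Hsd17b7 (0.94) and Cyp51 (0.84). These lists kept their calls with an estimated correlation, at adjusted p = 0.0065, 0.0038, 0.008 and 0.008 in the order given.

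The other 4 called lists pointed down in DN3a cells. Of 16 FOXO-linked and quiescence genes, 8 fell and 1 rose (9 and 1 adjusted over the list alone; camera adjusted p = 0.0033, and adjusted p = 0.048 with an estimated correlation). Gadd45a fell by 0.72 ± 0.10 SE and Pik3ip1 by 0.54 beside Bcl6, whereas Klf2, a quiescence factor, rose by 1.51. In DN to DP differentiation, the step towards CD4 CD8 double-positive cells, 6 of 11 fell and 0 rose (6 adjusted over the list alone; camera adjusted p = 0.0021, and adjusted p = 0.057 with an estimated correlation). Cd28 fell by 0.83 ± 0.11 SE, Cd8b1 by 0.79, Satb1 by 0.52 and Rag2, a recombinase subunit, by 0.51. In V(D)J recombination 4 of 9 fell, 5 adjusted over the list alone (camera adjusted p = 0.0096, and adjusted p = 0.051 with an estimated correlation). They included the end-joining genes Xrcc6 (-0.51) and Lig4 (-0.43) and Dntt (-0.41 ± 0.07 SE), which adds untemplated nucleotides. In G2/M 5 of 17 fell, 6 adjusted over the list alone (camera adjusted p = 0.016, and adjusted p = 0.057 with an estimated correlation), such as Cenpa (-0.50 ± 0.07 SE) and Kif23 (-0.32). Cdc25c (-0.53) and Nusap1 (-0.40) fell too, but other probes gave -0.10 for Cdc25c and 0.00 and 0.10 for Nusap1. Cdc25c was above background on 1 of 4 IL7-treated and 2 of 4 untreated arrays. The calls of Cdc25c, Nusap1 and Kif23 were lost under 8, 5 and 5 alternatives. The G2/M call ended without background correction (adjusted p = 0.051) and with the authors' values (adjusted p = 0.053).

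The remaining 17 lists did not pass in DN3a cells, with camera adjusted p of 0.17 or more. In glycolysis 5 of 15 rose, led by Hk2 (1.23), and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.17). In Notch targets 4 of 9 rose, among them Hes1 (0.44), and 1, Notch3 (-0.52), fell (4 and 3 adjusted over the list alone). The Notch median was -0.20, against a mean of 0.01 and an upward test (camera adjusted p = 0.67). In the BCL2 family 2 of 11 rose and 1, Bbc3 (-0.33), fell (2 and 2 adjusted over the list alone). The medians of the BCL2 family (-0.05) and of receptor-induced early genes (-0.05) opposed their means (0.44 and 0.07) and their upward tests (camera adjusted p = 0.48 and 0.76). Among the receptor-induced early genes, 2 of 12 rose, led by Fos (1.32, above background on 2 of 4 untreated arrays), and 1, Dusp6 (-0.54), fell. In the interferon response 4 of 14 rose, such as Ifit3 (0.68), and 1, Rsad2 (-0.85), fell (camera adjusted p = 0.51). Of 21 genes of G1/S and DNA replication, 2 rose and 2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.76). Jak1 (-0.53) was the only 1 of 8 cytokine receptor and JAK-STAT components past the threshold (0 adjusted over the list alone; camera adjusted p = 0.42). Of 7 heat shock genes 0 passed limma (camera adjusted p = 0.76), with 2 up and 2 down both adjusted over the list alone and at an unadjusted p under 0.05.

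Among mature T cell markers 2 of 7 rose with IL7 in DN3a cells, such as Ctla4 (0.97), and 2 fell, such as Cd6 (-0.83) (camera adjusted p = 0.76). Among dendritic cell markers 1 of 4, Irf8 (0.66), rose and 2 fell (camera adjusted p = 0.48). Of 4 NK and cytotoxic markers, 1, Nkg7 (0.78), rose and 1 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.76), and 2 of 4 gamma-delta T cell markers fell (camera adjusted p = 0.17). The myeloid marker Lyz2 fell by 0.92 (1 of 5 myeloid markers, camera adjusted p = 0.44), and Hhex fell by 0.36 (1 of 5 early thymic progenitor markers, camera adjusted p = 0.22). Of the 3 erythroid, 3 B cell and 3 thymic stroma markers, 0 passed limma (1, 0 and 1 at an unadjusted p under 0.05; camera adjusted p = 0.73, 0.79 and 0.79). The stroma median of 0.03 opposed its mean of -0.06.

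Over all genes, IL7 changed 1850 in DN3a cells, 833 higher and 1017 lower, and 1792 of them moved the same way in all 4 sorts. At least 2-fold changes were mostly upward, with 112 higher and 34 lower. Fits without the pairing block called 905 genes (461 higher and 444 lower), and fits without 1 sort called 1210 to 1392, the lowest without sort 2. The paired test without moderation gave 478 genes after adjustment (261 higher and 217 lower) and 2372 at an unadjusted p under 0.05, where limma gave 2897. Leaving out sorts 1 and 3 left 616 (325 and 291), so the excess of falls did not hold in every setting.

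**Figure D2:**
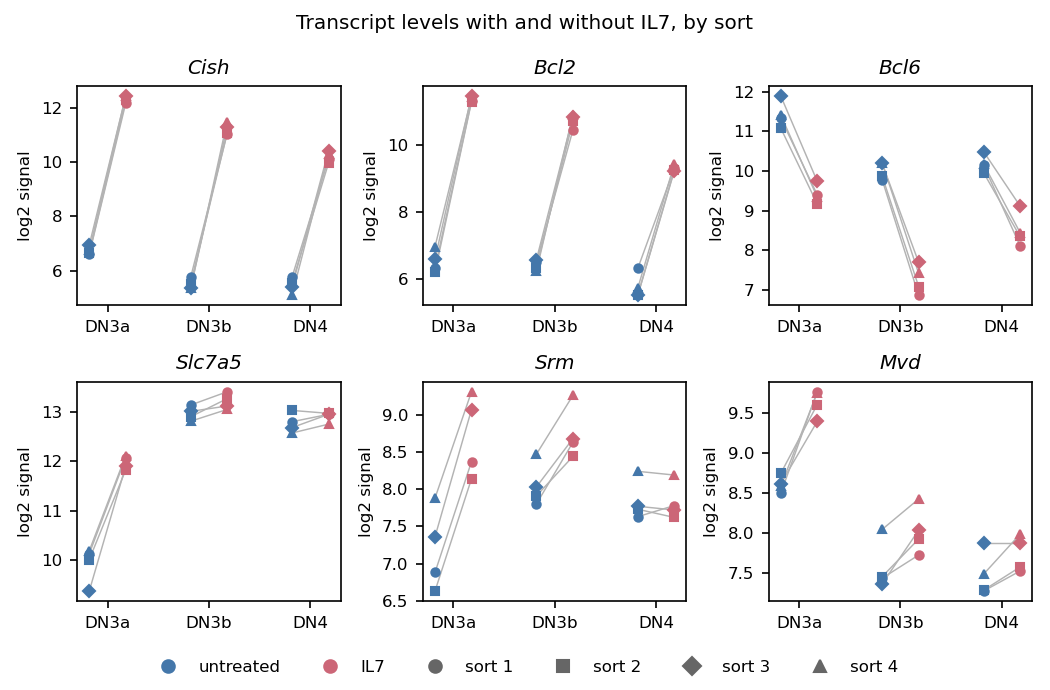
Log2 signal (vertical axis) of Cish, Bcl2, Bcl6, Slc7a5, Srm and Mvd in untreated and IL7-treated cultures (horizontal axis) of the 3 subsets, with a line for each of the 4 sorts. Mean Cish signals went from 6.74 to 12.33 in DN3a cells, from 5.50 to 11.22 in DN3b cells and from 5.46 to 10.20 in DN4 cells.

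In DN3b cells IL7 raised Socs2 at least 55.6-fold (limma adjusted p = 1.6e-10, n = 4 culture pairs) and Cish 52.6-fold (log2 change 5.72 ± 0.15 SE, adjusted p = 1.4e-10). Bcl2 rose 19.9-fold (log2 change 4.31 ± 0.14 SE, adjusted p = 7.6e-10). The transcription factor gene Bhlhe40 was at least 14.1-fold higher, the orphan receptor gene Gpr83 at least 9.9-fold and Il18r1 at least 7.43-fold, and Osm (10.3-fold) and Map3k8 (9.77-fold) rose as well. Bcl6 fell by 2.74 ± 0.10 SE on the log2 scale, Actn2 by 1.73 ± 0.11 SE and Pou2af1, a transcriptional coactivator, by 1.65 ± 0.15 SE. Acot5 (-1.35), Prag1 (-1.28), Cpa3 (-1.25), Gal (-1.18) and Grb7 (-1.11) were the next largest falls, with Gal above background on 2 of 4 IL7-treated arrays. Of the genes considered in advance, Pim1 rose 2.74-fold, Socs1 2.25-fold, Bcl2l1 1.7-fold and Mcl1 1.31-fold (adjusted p = 0.03, a call lost under 9 alternatives). Il7r fell by 0.63 ± 0.18 SE (adjusted p = 0.043, and 0.073 at another probe) and Ptcra, the pre-T cell receptor alpha chain gene, by 0.68 ± 0.19 SE (adjusted p = 0.04, lower in 3 of 4 sorts), calls lost under 8 and 6 alternatives. Myc was at -0.22 ± 0.13 SE (adjusted p = 0.38) and Rag1 at -0.10 (adjusted p = 0.73).

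5 lists passed camera in DN3b cells. In the IL7 and STAT5 response 12 of 14 rose and 0 fell (12 adjusted over the list alone; camera adjusted p = 2.1e-22, and adjusted p = 0.004 with an estimated correlation), with Socs3 up by 2.07 and Lta by 1.83. Of 16 FOXO-linked genes, 6 fell, among them Bcl6 and Pik3ip1, and 1, Klf2 (1.31), rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.0016, and adjusted p = 0.058 with an estimated correlation). In amino acid supply and ATF4, 7 of 22 rose, among them Trib3 (1.47), Cebpb (1.47) and Chac1 (1.36), and 0 fell (10 adjusted over the list alone; camera adjusted p = 8.1e-05, and adjusted p = 0.058 with an estimated correlation). Ribosome biogenesis genes passed with 2 of 24 risen, Srm (0.70) and Nop58 (0.23) (2 adjusted over the list alone; camera adjusted p = 0.0025, and adjusted p = 0.21 with an estimated correlation). The Nop58 call was lost under 12 alternatives, and other Srm probes gave 0.30 and 0.57 (limma adjusted p = 0.3 and 0.0013). Cholesterol synthesis passed with 4 of 18 risen, led by Hsd17b7 (0.58) and Mvd (0.45) (5 adjusted over the list alone; camera adjusted p = 0.047, and adjusted p = 0.28 with an estimated correlation). In total 865 genes changed in DN3b cells, 423 higher and 442 lower, 850 of them in the same direction in all 4 sorts. Without the pairing block 417 genes were called (246 higher and 171 lower), and the separate fit of the 8 DN3b arrays called 495 (289 and 206). Without 1 sort 507 to 637 were called (297 and 230 of 527 without sort 2, 291 and 216 of 507 without sort 4). Unmoderated paired tests called 52 after adjustment (39 and 13; 1432 at an unadjusted p under 0.05, against 1879 by limma), and leaving out sorts 1 and 3 left 348 (200 and 148).

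In DN4 cells IL7 raised Cish 26.7-fold (log2 change 4.74 ± 0.15 SE, n = 4 culture pairs, limma adjusted p = 2.4e-09, 3 of 4 untreated arrays above background) and Socs2 at least 11.2-fold (adjusted p = 1.6e-08). Bcl2 rose 11.6-fold (log2 change 3.54 ± 0.14 SE, adjusted p = 1e-08), with sort 1 apart at 3.00 against 3.71 to 3.74. Gpr83 rose 8.72-fold, with 1 of 4 untreated arrays above background, the kinase gene Sgk1 8.26-fold, Osm 6.26-fold, Socs3 5.78-fold and Bhlhe40 at least 3.8-fold (adjusted p = 2e-08). Bcl6 fell by 1.69 ± 0.10 SE on the log2 scale (adjusted p = 3.3e-07). The transcription factor genes Gfi1b (-0.84 ± 0.13 SE), Lef1 (-0.82 ± 0.12 SE) and Id3 (-0.68 ± 0.15 SE) fell too, as did Actn2 (-0.83), B3gnt8 (-0.74), Acot5 (-0.66) and Rapgef3 (-0.65). Pim1 rose 2.6-fold, with sort 2 apart at 0.54 against 1.61 to 1.73, Socs1 1.77-fold (adjusted p = 0.025) and Bcl2l1 1.42-fold (adjusted p = 0.03). The calls of Socs1 and Bcl2l1 were lost under 6 and 9 alternatives, and another Bcl2l1 probe gave 0.27 (adjusted p = 0.19). Id3 lost its call under 8 alternatives, and other probes of Lef1 and B3gnt8 gave -0.22 and -0.27 (adjusted p = 0.62 and 0.7). Mcl1 (0.39, adjusted p = 0.079), Ptcra (-0.72, adjusted p = 0.082), Myc (-0.24, adjusted p = 0.56), Rag1 (-0.18, adjusted p = 0.66) and Il7r (-0.08, adjusted p = 0.94, and 0.01 without sorts 1 and 3) did not pass.

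4 lists passed camera in DN4 cells. In the IL7 and STAT5 response 11 of 14 rose and 0 fell (12 adjusted over the list alone; camera adjusted p = 2.7e-28, and adjusted p = 0.0016 with an estimated correlation), including Lta (1.49). Of 7 mature T cell markers, 2 rose, among them the inhibitory receptor gene Ctla4 (2.02 ± 0.09 SE), and 1, Itgae (-0.52, with 0.11 and 0.13 at dimmer probes of Itgae), fell (2 and 1 adjusted over the list alone). The camera test of these markers gave adjusted p = 0.0045 (adjusted p = 0.13 with an estimated correlation). The Itgae call was lost under 14 alternatives, and a further Itgae probe gave -0.78 (limma adjusted p = 0.072). In V(D)J recombination only Dntt (-0.38 ± 0.07 SE) of 9 passed (2 adjusted over the list alone; camera adjusted p = 0.019, and adjusted p = 0.13 with an estimated correlation). The Dntt call was lost under 9 alternatives. In amino acid supply and ATF4, Chac1 (1.35), Cebpb (0.98) and Trib3 (0.77) rose and Ddit4 (-0.44) fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.024, and adjusted p = 0.33 with an estimated correlation). For ribosome biogenesis, 0 of 24 genes passed limma (0 adjusted over the list alone, 2 at an unadjusted p under 0.05; camera adjusted p = 0.45), with Ppan at 0.31 (adjusted p = 0.69). For cholesterol synthesis it was 0 of 18 (0 adjusted over the list alone, 5 up and 1 down at an unadjusted p under 0.05; camera adjusted p = 0.28), with Insig1 at -0.50 (adjusted p = 0.21). FOXO-linked genes, with 1 risen, Klf2 (1.35 ± 0.10 SE), and 1 fallen, Bcl6, did not pass as a list (1 and 4 adjusted over the list alone; camera adjusted p = 0.28).

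In total 215 genes changed in DN4 cells, 164 higher and 51 lower, and 214 of them moved the same way in all 4 sorts. The split was 190 higher and 99 lower without background correction and 191 and 99 with the authors' values. Granulocyte transcripts set these 4 sorts apart in both treatments, with S100a8 at 5.25, 12.25, 12.15 and 7.60 in the IL7-treated arrays and no change with IL7 past the threshold (0.14, adjusted p = 0.9). Without the DN4 arrays of sorts 2 and 3, 101 genes were called (89 higher and 12 lower). Fits without the pairing block called 103 (94 and 9), and the separate fit of the 8 DN4 arrays 93 (84 and 9). Without sort 1, 2, 3 or 4 in turn the counts were 118, 112, 145 and 90, with 24, 17, 25 and 8 lower. A fit without sorts 1 and 3 called 61 (55 and 6). Few of the 51 falls were thus called in these settings. The test without moderation called 0 genes after adjustment and 880 at an unadjusted p under 0.05, where limma gave 1006.

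**Figure D3:**
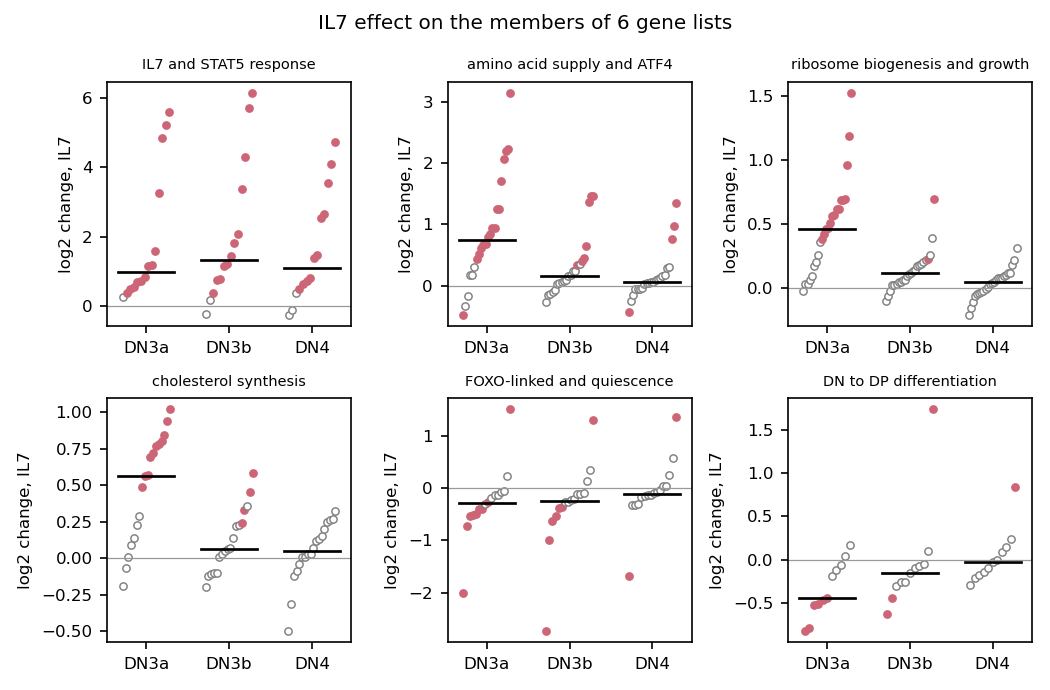
Log2 change with IL7 (vertical axis) of each measured member of 6 gene lists in DN3a, DN3b and DN4 cells (horizontal axis), with filled points for genes past the threshold and a line at each median. The median of the amino acid list went from 0.74 in DN3a cells to 0.16 in DN3b and 0.05 in DN4 cells, and that of the IL7 and STAT5 list from 1.00 to 1.34 and 1.10.

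The IL7 effects in the 3 subsets came from separate arrays, but the fit shared 1 variance per gene between them. This alone can raise the overlap of calls, and the numbers expected of independent lists leave it out. Of the genes that rose, DN3a and DN3b cells shared 288, where 40 would be shared by independent lists, and of those that fell 311, against 51. DN4 shared 148 risen and 43 fallen genes with DN3b cells, against 7.87 and 2.56, and 126 and 39 with DN3a cells, against 15.5 and 5.88. 164 genes were called in all 3 subsets, 125 of them risen in each, such as Cish, Bcl2 and Pim1, and 37 fallen in each, such as Bcl6. Calls of opposite direction in DN3a cells numbered 4 of the genes risen in DN3b, 4 of those risen in DN4 and 2 of those fallen in DN4.

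Whether IL7 acted differently between subsets was tested as a difference of effects. DN3b cells responded more strongly than DN3a cells for Gpr83 (difference of log2 changes 2.38 ± 0.32 SE, limma adjusted p = 0.0018, n = 4 sorts). Gpr83 was above background on 0 of 4 untreated arrays in both subsets, so the size of this difference was not measured. Further cases were Cd2 (1.70 ± 0.22 SE), Sgk1 (1.70 ± 0.34 SE) and the immediate early gene Fos (1.61 ± 0.32 SE, adjusted p = 0.021). Cd2 was above background on 0 DN3a arrays of either treatment and on 2 of 4 untreated DN3b arrays, and Fos on 2 of 4 untreated arrays in each subset. The difference ran the other way for Khdc1c (-1.92), Slc7a5 (-1.83 ± 0.15 SE, adjusted p = 8.8e-05), Chac1 (-1.80) and Gja1 (-1.72 ± 0.14 SE). Bcl6 fell further in DN3b cells (-0.73 ± 0.14 SE, adjusted p = 0.018). For Bcl2 (-0.54, adjusted p = 0.21), Cish (0.13, adjusted p = 0.83) and Myc (-0.72, adjusted p = 0.077) no difference passed. The same held for Il7r (-0.49, adjusted p = 0.39), Pim1 (0.28, adjusted p = 0.66), Socs1 (0.33, adjusted p = 0.57) and Ptcra (-0.48, adjusted p = 0.44).

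As groups, the growth lists rose less in DN3b than in DN3a cells. The median difference was -0.52 for amino acid supply and ATF4 (9 of 22 lower, 14 adjusted over the list alone, such as Mthfd2 at -1.36 and Asns at -1.20; camera adjusted p = 4.1e-15). It was -0.39 for ribosome biogenesis (8 of 24 lower, 11 adjusted over the list alone, such as Rrp12 at -1.06 and Srm at -0.83; camera adjusted p = 1.6e-10). For cholesterol synthesis it was -0.43 (4 of 18 lower, 10 adjusted over the list alone, such as Fdps at -0.67 and Sqle at -0.64; camera adjusted p = 7.6e-08). With an estimated correlation these 3 stayed called, at adjusted p = 0.0033, 0.014 and 0.014. G2/M differed by a median of 0.18 (Cenpa 0.45, 1 of 17 higher, 3 adjusted over the list alone; camera adjusted p = 0.00054, and adjusted p = 0.016 with an estimated correlation). DN to DP differentiation (median 0.16, 2 of 11 higher, Cd28 at 0.78; camera adjusted p = 0.0091) and mature T cell markers (median 0.61, 1 of 7 higher, Ctla4 at 1.17; camera adjusted p = 0.011) each reached adjusted p = 0.14 with an estimated correlation. Each had 3 members higher when adjusted over the list alone. In total 150 genes differed, 65 with a higher and 85 with a lower effect in DN3b cells. No gene passed limma without sorts 1 and 3, a count of 0 with 876 at an unadjusted p under 0.05, and 37 passed without the pairing block and 46 to 60 without any 1 sort, while a trended and robust variance gave 390.

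Between DN4 and DN3b cells fewer effects of IL7 differed. The falls of Bcl6 (1.05 ± 0.14 SE, limma adjusted p = 0.0039, n = 4 sorts), Actn2 (0.90), Prag1 (0.99) and Lypd6b (1.02) were smaller in DN4 cells. These calls were lost under 5, 8, 9 and 7 alternatives in the order given. Lypd6b was above background on 0 of 4 IL7-treated DN3b arrays and on 2 of 4 DN4 arrays of each treatment. The rises of Il18r1 (-3.20 ± 0.36 SE), Rab38 (-2.11 ± 0.18 SE) and Socs2 (-2.07 ± 0.25 SE) were smaller too, and Nav1 differed by -1.83 ± 0.22 SE, while a dimmer probe of Nav1 gave 0.33. Il18r1, Rab38 and Socs2 were above background on 0 of 4 untreated arrays in both subsets, and in IL7-treated DN4 cells Rab38 on 0 and Il18r1 on 1 of 4. Nav1 was above background on 1 of 4 DN4 arrays of each treatment. The sizes of these differences were therefore not measured exactly. The calls of Il18r1, Rab38, Socs2 and Nav1 were lost under 3, 1, 2 and 2 alternatives. The IL7 and STAT5 list had a lower effect in DN4 cells (median -0.31, 1 of 14 lower, and 1 higher and 5 lower adjusted over the list alone; camera adjusted p = 6.1e-05, and adjusted p = 0.19 with an estimated correlation). FOXO-linked genes had a median difference of 0.18 (1 of 16 higher, 3 adjusted over the list alone; camera adjusted p = 0.0018, and adjusted p = 0.12 with an estimated correlation). Amino acid genes had one of -0.12 with 0 of 22 past limma (0 adjusted over the list alone, 5 lower at an unadjusted p under 0.05; camera adjusted p = 0.0079, and adjusted p = 0.19 with an estimated correlation). In total 27 genes differed, 6 higher and 21 lower. The count was 0 without sorts 1 and 3 (936 at an unadjusted p under 0.05), and 6 without the DN4 arrays of sorts 2 and 3. It was 5 to 18 without any 1 sort, 16 without the pairing block and 107 with a trended and robust variance. Of the higher effects, 0 were called without the DN4 arrays of sorts 2 and 3, without sort 2 or without sort 4.

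Over the whole interval, 473 effects differed between DN4 and DN3a cells, 232 higher and 241 lower. Bcl2 rose less in DN4 cells (-1.31 ± 0.20 SE, limma adjusted p = 0.0023, n = 4 sorts), as did Cish (-0.85 ± 0.22 SE, adjusted p = 0.038), and Myc differed by -0.73 ± 0.19 SE (adjusted p = 0.038). Untreated DN4 levels ran from 5.52 to 6.32 for Bcl2 and from 5.10 to 5.77 for Cish. The lowest detected signals on those arrays were 5.16 to 5.32. In untreated DN3a cells Bcl2 stood at 6.21 to 6.97 and Cish at 6.61 to 6.95. Changes of dim probes are compressed, so the sizes of the Bcl2 and Cish differences were not measured exactly. Khdc1c (-3.22), Igf2 (-2.95 ± 0.20 SE), Il18r1 (-2.83) and Nav1 (-2.34) had the lowest fitted differences, with 0.26 at the dimmer Nav1 probe. Gpr183 (2.21 ± 0.23 SE) and Cpa3 (1.83), which fell in DN3a cells, and Gpr83 (1.96) and Socs3 (1.84 ± 0.15 SE), which rose more in DN4 cells, stood on the other side. Most of these sizes were not measured exactly. On untreated arrays, Khdc1c and Gpr183 were above background on 0 of 4 in DN4 cells, Gpr83 on 0 of 4 in DN3a cells, and Il18r1 on 0 of 4 in both. Igf2 and Cpa3 were above background on 2 of 4 untreated DN4 arrays and Nav1 on 1. Amino acid genes had a median difference of -0.63 (15 of 22 lower, 16 adjusted over the list alone, such as Slc7a5 at -1.94; camera adjusted p = 7.1e-17). Ribosome biogenesis had one of -0.40 (10 of 24 lower, 13 adjusted over the list alone, such as Srm at -1.55; camera adjusted p = 1.7e-12), and cholesterol synthesis one of -0.47 (8 of 18 lower, 10 lower and 1 higher adjusted over the list alone, such as Nsdhl at -0.76; camera adjusted p = 5.3e-09).

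With an estimated correlation those 3 lists stayed called, at adjusted p = 0.0022, 0.0086 and 0.0086. DN to DP differentiation stayed called too (median 0.38, 3 of 11 higher and 7 adjusted over the list alone, such as Cd28 at 1.07; camera adjusted p = 0.00031, and adjusted p = 0.045 with an estimated correlation), and so did G2/M (median 0.15, 4 of 17 higher and 6 adjusted over the list alone, such as Kif23 at 0.45; camera adjusted p = 0.00077, and adjusted p = 0.02 with an estimated correlation). The IL7 and STAT5 list had a median of -0.29 (5 of 14 lower and 1 higher, 7 and 1 adjusted over the list alone; camera adjusted p = 0.018, and adjusted p = 0.31 with an estimated correlation). FOXO-linked genes had a median of 0.24 with 0 of 16 past limma (0 adjusted over the list alone, 6 higher at an unadjusted p under 0.05). Their camera test gave adjusted p = 0.018, and adjusted p = 0.088 with an estimated correlation. Mature T cell markers had a median of 0.35 (3 of 7 higher, 3 adjusted over the list alone; camera adjusted p = 0.0048, and adjusted p = 0.088 with an estimated correlation). Without the DN4 arrays of sorts 2 and 3, which carried the most granulocyte transcripts, 137 effects differed, without the pairing block 128, without any 1 sort 167 to 213, and without sorts 1 and 3 24. More were called without background correction (728), with the authors' values (741) and with a trended and robust variance (743).

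**Figure D4:**
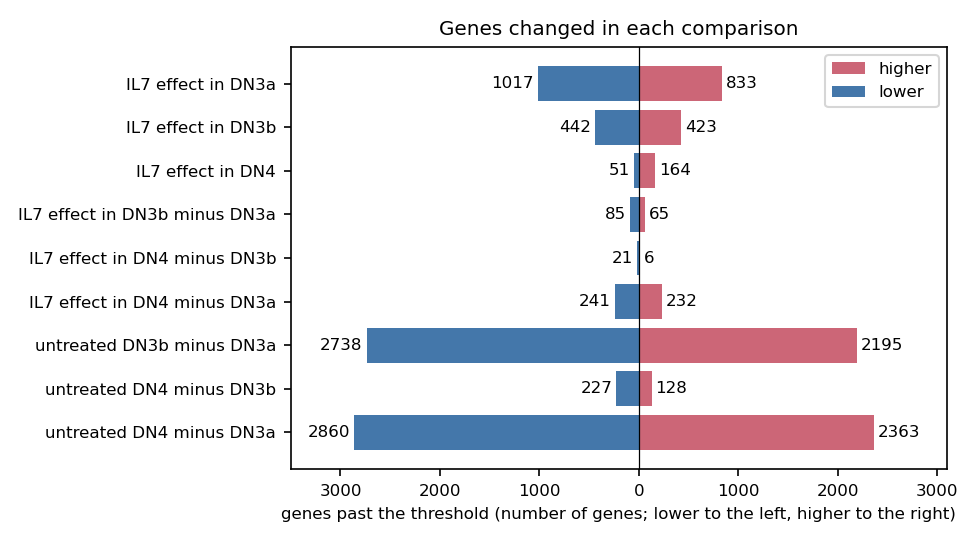
Numbers of genes (bars, from 0) that were higher or lower in each of the 9 comparisons at a limma adjusted p under 0.05. The IL7 effect in DN3a cells shows 833 higher and 1017 lower genes, that in DN4 cells 164 and 51, and untreated DN4 against DN3a cells 2363 and 2860.

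The design also allowed the untreated subsets to be compared. The gate genes served as checks. From DN3a to DN3b, Il2ra, which encodes CD25, was lower (-1.17 ± 0.17 SE, limma adjusted p = 0.00017, n = 4 sorts) and Tfrc, which encodes CD71, was higher (0.79 ± 0.10 SE, adjusted p = 9e-05). Kif18b rose 19.4-fold (log2 change 4.28 ± 0.21 SE), Kif2c 18.9-fold, Plk1 16.1-fold (4.01 ± 0.15 SE, adjusted p = 3.5e-08), Cdca3 14.5-fold and Cdc25c 17-fold, with Cdc25c above background on 2 of 4 DN3a arrays. Pif1, a DNA helicase gene, rose 16.8-fold, Depdc1b 16.6-fold and the peroxiredoxin gene Prdx4 was higher by 3.99 ± 0.16 SE on the log2 scale. The neuropeptide gene Gal fell by 4.97 ± 0.20 SE on the log2 scale, the integrin genes Itgae by 4.87 and Itgb4 by 4.04, the sodium channel subunit gene Scn4b by 4.87 and Socs3 by 3.84. Ctsw (-3.57) and Rps6kl1 (-3.39, above background on 2 of 4 DN3b arrays) fell as well, and Ccl4 was at least 8.19-fold lower (adjusted p = 2.1e-08).

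In this step 17 of 17 G2/M genes rose, with a median of 3.23 (17 adjusted over the list alone; camera adjusted p = 3.9e-12). So did 21 of 21 G1/S genes, with a median of 1.69, such as Rrm2 (2.78) and Tyms (2.49) of nucleotide synthesis (21 adjusted over the list alone; camera adjusted p = 6.7e-12). In ribosome biogenesis 20 of 24 rose and 0 fell, such as Odc1 (1.62; 20 adjusted over the list alone; camera adjusted p = 3.8e-08). In amino acid supply 18 of 22 rose and 3 fell, such as Asns (3.15) and Slc7a5 (3.06; 18 and 3 adjusted over the list alone; camera adjusted p = 3.2e-07). Of 18 cholesterol synthesis genes, 13 fell and 2 rose, with Hsd17b7 at -1.55 and Dhcr7 at -1.52 (13 and 2 adjusted over the list alone; camera adjusted p = 0.0044). Of 9 Notch targets 7 fell and 1 rose, with Notch3 at -3.28 and Hes1 at -3.22 (7 and 1 adjusted over the list alone; camera adjusted p = 0.014, and 0.03 without the gate gene Il2ra). Of 14 interferon response genes 10 fell and 2 rose (11 and 2 adjusted over the list alone; camera adjusted p = 0.011). These 7 lists lost their calls with an estimated correlation, at adjusted p = 0.11 for G2/M, G1/S, ribosome biogenesis, amino acid supply and the interferon response, 0.31 for cholesterol synthesis and 0.29 for Notch targets. In total 4933 genes differed, 2195 higher and 2738 lower in DN3b cells, 4760 of them the same way in all 4 sorts, and 564 rose and 574 fell at least 2-fold.

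From DN3b to DN4, Il2ra was lower again (-2.86 ± 0.17 SE, limma adjusted p = 4.3e-05, n = 4 sorts, 1 of 4 DN4 arrays above background) and Tfrc was lower (-0.74 ± 0.10 SE, adjusted p = 0.0031). Cd8b1, the CD8 beta chain gene, rose 3.48-fold (log2 change 1.80 ± 0.14 SE, adjusted p = 0.00023), with sort 4 apart at 2.07 against 1.70 to 1.72. Cd2 rose 3.48-fold (1.80 ± 0.16 SE) and Slamf1 3.24-fold (1.69 ± 0.13 SE), both adhesion or signalling receptors and each above background on 2 of 4 DN3b arrays. Slfn1 rose 3-fold, Gramd3 2.82-fold with 1 of 4 DN3b arrays above background, Rmnd5a 2.52-fold, Gpr162 at least 1.85-fold and Tspan32 at least 1.76-fold. Scin, an actin-severing protein gene, fell by 2.93 ± 0.16 SE (adjusted p = 4.3e-05), Nfe2 by 2.13, the cell cycle inhibitor gene Cdkn1a by 2.06 ± 0.20 SE on the log2 scale. Cpa3 fell by 1.98 with 2 of 4 DN4 arrays above background, Nkg7 by 1.88, Casp1 by 1.82, Ifitm2 by 1.74 and Itgb4 by 1.71.

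9 lists passed camera from DN3b to DN4, and all 9 lost their calls with an estimated correlation. In DN to DP differentiation 4 of 11 rose and 0 fell, such as Rag1 (0.71 ± 0.11 SE) and Satb1 (0.38) (6 adjusted over the list alone; camera adjusted p = 3e-05, and adjusted p = 0.058 with an estimated correlation). V(D)J recombination passed with 1 of 9 risen, Rag1 (2 adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.13 with an estimated correlation). Rag1 is also on the DN to DP differentiation list. Of 9 Notch targets 4 fell, such as Notch3 (-1.09) and Hes1 (-1.14, above background on 2 of 4 DN4 arrays; 4 adjusted over the list alone; camera adjusted p = 3e-05, and adjusted p = 0.13 with an estimated correlation). Il2ra is 1 of the 4, and its fall was set by the CD25 gate. Without it 3 of 8 fell (camera adjusted p = 0.0025). Of 12 receptor-induced early genes 3 fell, among them Cd69 (-1.23; 5 adjusted over the list alone; camera adjusted p = 0.005, and adjusted p = 0.13 with an estimated correlation). Of 4 gamma-delta T cell markers 2 fell, Cd163l1 (-0.95) among them (camera adjusted p = 0.005), and of 5 early progenitor markers 1 fell, Mef2c (-0.57; camera adjusted p = 0.041), each at adjusted p = 0.24 with an estimated correlation. Ribosome biogenesis had a median of -0.15 with 0 of 24 past limma (0 adjusted over the list alone, 1 higher and 5 lower at an unadjusted p under 0.05). Its camera test gave adjusted p = 0.0065, and adjusted p = 0.27 with an estimated correlation. Amino acid supply had a median of -0.19 (2 of 22 higher and 3 lower, 2 and 5 adjusted over the list alone; camera adjusted p = 0.037, and adjusted p = 0.26 with an estimated correlation). Myeloid markers passed upwards. S100a8 (3.57 ± 0.79 SE, adjusted p = 0.036) was above background on 3 of 4 DN4 and 2 of 4 DN3b arrays. It was the 1 of 5 members risen (3 adjusted over the list alone; camera adjusted p = 0.015, and adjusted p = 0.26 with an estimated correlation). In sorts 1 to 4 S100a8 stood at 4.45, 12.39, 12.29 and 7.58 in DN4 against 4.53, 5.81, 7.66 and 4.42 in DN3b cells, higher in 3 of 4 sorts. The call was lost under 10 alternatives, with 1.83 without the DN4 arrays of sorts 2 and 3 (adjusted p = 0.22).

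G1/S and G2/M genes, with 0 of 21 and 0 of 17 past limma and 1 each at an unadjusted p under 0.05, did not pass as lists in this step (camera adjusted p = 0.41 and 0.23). In total 355 genes differed between untreated DN4 and DN3b cells, 128 higher and 227 lower in DN4, 354 of them the same way in all 4 sorts. The count was 103 without the DN4 arrays of sorts 2 and 3, 166 without the sort block, 231 on the 8 arrays alone and 66 without sorts 1 and 3. Without sort 1, 2, 3 or 4 in turn it was 176, 140, 225 and 110, and with the sort as a block over all 24 arrays 538.

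From DN3a to DN4, Il2ra was lower (-4.03 ± 0.17 SE, limma adjusted p = 3.2e-08, n = 4 sorts). Tfrc was at 0.05 ± 0.10 SE (adjusted p = 0.72), higher in 2 of 4 sorts and at -0.08 without sort 3. The CD71 difference of the gates, low in DN3a and high in DN4 cells, was therefore not seen in Tfrc transcripts. Prdx4 rose 24.5-fold (4.61 ± 0.16 SE, adjusted p = 1.4e-08), Pdlim4 at least 17.7-fold and Cd8b1 22.7-fold (4.51 ± 0.14 SE). Kif2c (20.1-fold), Depdc1b (19.9-fold), Kif18b (19.8-fold), Cdc25c (19.4-fold) and Plk1 (17.6-fold) rose with them. Scn4b fell by 6.05 ± 0.18 SE on the log2 scale, with sort 4 apart at -5.49 against -6.27 to -6.20, and Scin by 5.91 ± 0.16 SE, with sort 2 apart at -6.19 against -5.83 to -5.79. Itgb4 fell by 5.75, Gal by 5.30, Socs3 by 5.22, Itgae by 4.85, Nkg7 by 4.83 and Nfe2 by 4.58. In total 5223 genes differed, 2363 higher and 2860 lower in DN4 cells.

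The 8 lists that passed between DN4 and DN3a cells all lost their calls with an estimated correlation, at adjusted p = 0.15 or more, and their counts were the same when adjusted over the list alone. In G2/M 17 of 17 rose (median 3.36; camera adjusted p = 2.6e-11) and in G1/S 21 of 21 (median 1.56; camera adjusted p = 3.1e-11), such as Birc5 (3.92) and Rrm2 (3.05). In ribosome biogenesis 19 of 24 rose and 0 fell (camera adjusted p = 3.3e-06), and in amino acid supply 17 of 22 rose and 2 fell (camera adjusted p = 2.5e-06). Of 9 Notch targets 8 fell and 1 rose (Notch3 at -4.37; camera adjusted p = 0.0028). Without Il2ra, whose fall was set by the CD25 gate, 7 of 8 fell (camera adjusted p = 0.0087). Of 18 cholesterol synthesis genes 13 fell and 2 rose (Hsd17b7 at -1.81; camera adjusted p = 0.0044). Of 14 interferon response genes 11 fell and 2 rose (Oasl2 at -2.14; camera adjusted p = 0.0065), and of 4 dendritic cell markers 4 fell (camera adjusted p = 0.029). The granulocyte transcript S100a8 was 2.07 ± 0.79 SE higher in DN4 than in DN3a cells (adjusted p = 0.045), and higher in 3 of 4 sorts. This call was lost under 9 alternatives, and without the DN4 arrays of sorts 2 and 3 it was at 0.33 (adjusted p = 0.68).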

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

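The tests of probe signals near the top of the scale, of levels already raised in untreated DN4 cells and of the source of the granulocyte transcripts were chosen after their results had been seen.

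In 9 of 192 groups of 4 sorts, 1 sort lay far from the others by Dixon's test, where chance gives about 1 in 20. For the IL7 effect in DN3a cells these were Osm, at 2.59 in sort 3 against 3.43 to 3.54, and Blk, at -1.22 in sort 1 against -1.82 to -1.72. For the IL7 effect in DN4 cells they were Bcl2, at 3.00 in sort 1 against 3.71 to 3.74, and Pim1, at 0.54 in sort 2 against 1.61 to 1.73. Between untreated subsets they were Cd8b1 in DN4 against DN3b cells, at 2.07 in sort 4 against 1.70 to 1.72, and in DN4 against DN3a cells Scn4b, at -5.49 in sort 4 against -6.27 to -6.20, and Scin, at -6.19 in sort 2 against -5.83 to -5.79. The mean level of mature T cell markers in untreated DN4 cells was 7.0 in sort 3 against 7.28 to 7.29. That of thymic stroma markers in IL7-treated DN3a cells was 8.50 in sort 2 against 8.45 to 8.46.

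The effect of IL7 differed between subsets by limma's test of the difference. Between DN3b and DN3a cells 150 genes differed, with 2.38 for Gpr83, 1.70 for Sgk1, 1.70 for Cd2, 1.61 for Fos, -1.92 for Khdc1c, -1.83 for Slc7a5, -1.80 for Chac1 and -1.72 for Gja1. Between DN4 and DN3b cells 27 differed, with 1.05 for Bcl6, 1.02 for Lypd6b, 0.99 for Prag1, 0.90 for Actn2, -3.20 for Il18r1, -2.11 for Rab38, -2.07 for Socs2 and -1.83 for Nav1. Between DN4 and DN3a cells 473 differed, with 2.21 for Gpr183, 1.96 for Gpr83, 1.84 for Socs3, 1.83 for Cpa3, -3.22 for Khdc1c, -2.95 for Igf2, -2.83 for Il18r1 and -2.34 for Nav1. Gpr83, Cd2, Lypd6b, Il18r1, Rab38 and Socs2, and between DN4 and DN3a cells Khdc1c and Gpr183, were above background on 0 of 4 arrays in at least 1 group compared, so their sizes were not measured exactly.

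Gene lists that differed by camera are given by the median of their members. From DN3a to DN3b cells the medians were 0.16 for DN to DP differentiation, -0.43 for cholesterol synthesis, -0.39 for ribosome biogenesis, -0.52 for amino acid supply, 0.18 for G2/M and 0.61 for mature T cell markers, and with an estimated correlation the first and the last of these lost their calls. From DN3b to DN4 cells they were -0.31 for the IL7 and STAT5 response, 0.18 for FOXO-linked genes and -0.12 for amino acid supply, and with an estimated correlation these 3 lost their calls. From DN3a to DN4 cells they were -0.29 for the IL7 and STAT5 response, 0.24 for FOXO-linked genes, 0.38 for DN to DP differentiation, -0.47 for cholesterol synthesis, -0.40 for ribosome biogenesis, -0.63 for amino acid supply, 0.15 for G2/M and 0.35 for mature T cell markers, where the IL7 and STAT5, FOXO-linked and mature T cell lists lost theirs.

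Probes without a gene symbol were not used in the comparisons, and 781 of them passed the filter. By limma 150, 57 and 10 of them changed with IL7 in DN3a, DN3b and DN4 cells. Differences of the IL7 effect were called for 11 between DN3b and DN3a, 2 between DN4 and DN3b, and 35 between DN4 and DN3a cells. Between untreated subsets 410 differed from DN3a to DN3b, 18 from DN3b to DN4 and 442 from DN3a to DN4.

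Chance assignment of arrays was tested on the 35 splits of 8 values into 4 and 4, without the pairing. For 8 of the 9 comparisons only 1 split, the real one, gave as many genes. The real and the highest other counts were 649 and 6 for IL7 in DN3a, 324 and 4 in DN3b, 119 and 1 for the difference of DN3b from DN3a, 18 and 1 for DN4 from DN3b, and 395 and 0 for DN4 from DN3a. Between untreated subsets they were 4233 and 1 from DN3a to DN3b, 132 and 12 from DN3b to DN4, and 4496 and 1 from DN3a to DN4. For IL7 in DN4 cells 2 of the 35 splits gave as many, so this test did not exclude chance: the real split called 65 genes and the split of sorts 1 and 2 against sorts 3 and 4 called 397, which points to a structure of the sorts. That split left all 4 culture pairs whole. Among the 8 splits that part every pair, fitted with the pairs as blocks, the real one called 93 genes in DN4 cells and the highest other 0. In the same blocked fits the real counts were 1431, 495, 41, 11, 130, 4767, 231 and 5007 for the other comparisons in the order above, with 0 in the highest other split of each. A test over 8 splits cannot give a share under 0.05.

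IL7 changed fewer genes and with smaller effects in DN4 than in DN3a cells. Effects were compared on the 500 genes with the largest mean response of both subsets in 2 sorts, with the ratio of DN4 to DN3a taken from sorts left out of that choice and a bound of 0.8 set in advance. The highest of 6 ratios was 0.517, below the 0.8 that a larger spread between the DN4 pairs as the whole cause required. The fit already shared 1 variance per gene between the subsets, so such a spread would not have lowered the DN4 count alone. Among genes with log2 levels over 10 the highest ratio was 0.367, which argues against compression of dim probes by background. In sorts 1 and 4, where granulocyte transcripts in DN4 cells were lowest, the higher ratio was 0.557, which argues against granulocyte RNA as the whole cause. A difference between the subsets themselves stays open as a hypothesis, as do effects of the sort or culture that follow the subset.

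The ribosome biogenesis and amino acid lists rose less with IL7 in DN4 than in DN3a cells, and so did cholesterol synthesis. Of the 31 members of the first 2 lists that rose in DN3a cells, 0 lay within 1 log2 unit of the highest probe in DN4 cells (the highest at 14.16 against 15.94), which argues against signals near the top of the scale. To avoid sharing arrays, members that rose in DN3a cells were chosen in 2 sorts and their untreated levels compared in the other 2: at least 90.9% were higher in DN4 than in DN3a cells in both, over the 6 choices of sorts, against 36% to 38.9% of all genes and 38.5% to 48% of all that rose in the same sorts, so a level raised before IL7 may be part of the reason. Most members of the first 2 lists as a whole were higher too, so this share was not particular to those that IL7 raised. For the cholesterol genes chosen this way 0% were higher and 87.5% or more were lower, which argues against the same explanation there. Most of the cholesterol list as a whole was lower too. What limited the rise of the cholesterol genes stays open.

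DN4 cultures of sorts 2 and 3 carried the most granulocyte transcripts. Of 10 measured genes on a list of 18 granulocyte genes, 8 (Ngp, Camp, Ltf, Lcn2, Chil3, S100a8, S100a9 and Lyz2) were higher in both untreated DN4 arrays than in the 10 other untreated arrays. Elane and Mmp9 were not, and S100a8, S100a9, Lyz2 and Elane are also on the myeloid list. The 1.52% per gene that chance gives holds only for arrays fixed in advance. These arrays were chosen after their granulocyte transcripts had been seen, so that share does not apply here. The same 8 were also higher in both IL7-treated DN4 arrays of these sorts than in the IL7-treated DN4 arrays of the other sorts. This comparison was within DN4 cells only. The recurrence of the 8 on separate arrays argues against a fault of single arrays. RNA from granulocytes in the sorted cells is a candidate source, although the sort removed lineage-positive cells with antibodies not given in the sources used here, and no biological explanation was tested.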

How the results depend on the processing

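Leaving out the DN4 arrays of sorts 2 and 3, leaving out sorts 1 and 3, and testing the Notch list without the gate gene Il2ra were chosen after seeing the data. For named genes past the threshold, 8058 values under another setting kept the call in 7301 cases, lost it in 756 and reversed in 1. List calls were kept in 612 cases and lost in 87. Without Il2ra the Notch list kept its call from DN3a to DN3b, DN3b to DN4 and DN3a to DN4 (camera adjusted p = 0.03, 0.0025 and 0.0087). With an estimated correlation it lost the call in each of these (camera adjusted p = 0.27, 0.16 and 0.19). Slide as a block was not run, since the files give no slides, and genes removed by the strict filter give no value there. Signal over background (95th over 5th percentile, 19.28 to 33.59 per array) limits changes of dim genes. Unless fewer arrays explain a lower count, the cause was not tested.

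Without the replicate block, IL7 called 905, 417 and 103 genes in DN3a, DN3b and DN4 cells. The same fit called 37 differences of DN3b from DN3a, 16 of DN4 from DN3b and 128 of DN4 from DN3a, and 166 genes between untreated DN4 and DN3b cells. The pairing moved no other count by over 1.5 times. A block by sort over 24 arrays called 538 between untreated DN4 and DN3b cells. Separate fits called 495 with IL7 in DN3b, 93 in DN4, and 231 between untreated DN4 and DN3b cells. The paired test without moderation called 478, 52 and 0 genes with IL7 in the 3 subsets (2372, 1432 and 880 at an unadjusted p under 0.05), and 1 gene, Rplp1, had no value.

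For differences of the IL7 effect of DN3b from DN3a, DN4 from DN3b and DN4 from DN3a, and for untreated DN4 against DN3b cells, counts were 354, 99, 728 and 562 without background correction, 361, 105, 741 and 566 with the authors' values, and 390, 107, 743 and 567 with a trended and robust variance. Normexp gave 281 and 80 for the first 2, and the strict filter 237 for the first.

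Without each sort in turn, IL7 counts ran from 1210 to 1392 in DN3a, 507 to 637 in DN3b and 90 to 145 in DN4 cells, and the differences in the order above from 46 to 60, 5 to 18 and 167 to 213. Untreated counts ran from 4295 to 4634 from DN3a to DN3b, 110 to 225 from DN3b to DN4 and 4595 to 5021 from DN3a to DN4. Without the DN4 arrays of sorts 2 and 3, counts were 101 for IL7 in DN4, 6 and 137 for its differences from DN3b and DN3a, and 103 between untreated DN4 and DN3b cells. Without sorts 1 and 3, IL7 called 616, 348 and 61, limma's differences were 0, 0 and 24 (876 and 936 at an unadjusted p under 0.05 for the first 2), and untreated DN4 against DN3b 66.

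Signs turned for 3 genes. Nusap1 with IL7 in DN3a cells was at 0.10 with the probe of highest F. Tfrc in untreated DN4 against DN3a cells was at -0.01 with array weights, -0.06 without the DN4 arrays of sorts 2 and 3 and -0.12 without sorts 1 and 3, and ran from -0.08 to 0.14 without each sort in turn. Il7r with IL7 was at 0.01 in DN4 cells without sorts 1 and 3 and ran from -0.38 to 0.08 in DN3a cells without each sort in turn.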

Other observations

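The comparison of IL7 effects in DN3a cells with the DN3b to DN4 step was chosen before its result was seen, and the split of sorts by Hba-a1 was chosen after.

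Several lists that did not pass camera between untreated DN3a and DN3b cells held members that moved both ways. Of all 8820 genes, 4933 passed the threshold in this comparison, so such counts need not set these lists apart. In the BCL2 family 6 of 11 fell and 2 rose (camera adjusted p = 0.22), with Bmf, a pro-apoptotic member, at -2.23 ± 0.16 SE and Mcl1 at -1.06 ± 0.10 SE (limma, n = 4 sorts). Of 15 glycolysis genes 7 rose and 4 fell (camera adjusted p = 0.18), with Tpi1 at 1.77 ± 0.07 SE, Pfkp at 1.77 and Aldoc at -1.74. In the FOXO-linked list 9 of 16 fell and 2 rose (camera adjusted p = 0.14), with Pik3ip1 at -1.91, Txnip at -1.42 and Bcl6 at -1.42, while Il7r was 1.31 ± 0.10 SE higher. Of 7 heat shock genes 5 rose, such as Hspd1 (1.37) and Hsph1 (1.35), and 1 fell (camera adjusted p = 0.058). In cytokine receptor and JAK-STAT components 5 of 8 fell, such as Jak1 (-1.05), and 1 rose (camera adjusted p = 0.18).

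In the step from untreated DN3b to DN4 cells Bcl2l1, which protects double-positive thymocytes from apoptosis, rose by 1.0 on the log2 scale (± 0.11 SE, limma adjusted p = 0.001, n = 4 sorts) and its antagonist Bcl2l11 fell by 0.60 ± 0.08 SE. Il7r fell by 0.63 ± 0.10 SE, and the mature T cell marker Cd6 rose by 1.21 ± 0.12 SE, with -0.10 at a dimmer probe of Cd6. Other probes of Bcl2l1 gave 0.60 and 0.52, neither past the threshold (limma adjusted p = 0.21 and 0.05). Those of Bcl2l11 gave -0.22 and -0.67 (adjusted p = 0.34 and 0.019), and another Il7r probe gave -0.59 (adjusted p = 0.11). From untreated DN3a to DN3b cells 2 of 3 thymic stroma markers fell, Cldn4 (-3.23 ± 0.13 SE) and Cdh1 (-2.32 ± 0.16 SE), while the list did not pass (limma, n = 4 sorts, camera adjusted p = 0.16).

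A hypothesis was that IL7 moves DN3a transcripts against the direction of the DN3b to DN4 step. Across genes, which are not independent replicates, the correlation of the IL7 effect in DN3a cells with the untreated step ran from -0.11 to -0.053 over 6 choices of separate sorts. Over all sorts Pearson's correlation was -0.096 and Spearman's -0.063. Of 177 genes called in both, 100 moved in opposite directions, with 59 up then down (21.4 if independent) and 41 down then up (14.8). However, 67 were down in both (26.2) and 10 up in both (12.1). The explanation and its absence cannot be told apart, since the correlations were small and negative, and the genes down in both exceeded independence as did those of opposite direction.

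Hba-a1 was detected on 12 of 12 arrays of sorts 1 and 3 and on 0 of 12 arrays of sorts 2 and 4, in each subset and with or without IL7. Of 2 other erythroid genes, Klf1 was detected on 1 of the 12 arrays of sorts 1 and 3 and 3 of those of sorts 2 and 4, and Epor on 9 and 3.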
